A study of Mus musculus with 3 samples.

How the data were processed

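Gene expression was measured on 3 Agilent 2-colour mouse arrays with 60-base probes, 1 array for each polarised T cell type. On every array the Cy3 channel held RNA of naive CD4 T cells and the Cy5 channel held RNA of Th2, Th9 or induced regulatory T cells (iTreg). Per the labels, each comparison had 1 biological replicate, and the dyes were not swapped. The 3 arrays sat on 1 slide, so a cell type and an array position cannot be told apart. The labels do not say whether the 3 naive channels came from 1 RNA extract.

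The deposited scanner files hold, per the file headers, spot and background intensity in both channels, quantified with Agilent Feature Extraction 11.0.1.1. The submitters' processing notes name version 9.3.2.1 of the same software. The deposited files also hold processed intensity values, which the scanner software had background-subtracted and dye-normalised. Beside them they give, per the file headers, a log10 ratio of Cy5 over Cy3 with its log10 error and a p-value from the software's error model, which covers error within 1 array. The deposited series values were found to hold the log2 ratio of the processed signals plus 1 constant per array (0.056, 0.021 and 0.037 for Th2, Th9 and iTreg). The constant held within 0.001 for 99.7%, 99.7% and 99.8% of probes, and ratios were floored at 0.01.

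The median spot and background intensities were taken for the main values. The plan had named mean intensities, which the files do not contain. Intensities were background-corrected by the normexp method with an offset of 50, and log2 ratios were normalised by loess within each array (limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8). Control spots and spots called outliers by the scanner software had no weight in the loess, and outlier spots were then dropped. Spots of 1 probe were averaged. Further steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

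Probes were matched by RefSeq accession, without its version, to mouse genes of assembly GRCm38.p6. The array design was built on an older assembly, so only names were used and no coordinates are given. Of 39429 probes, 26055 (66.1%) matched, for 19741 genes, and 13374 probes had no match. For the 5264 genes with several probes, the probe with the highest mean log2 intensity was used, whatever its ratio. A gene counted as measured when its spots were well above background in both channels. Where only 1 channel was above background, a bound was set from the background level of the other channel, and such a value is given as "at least". Between cultures, log2 ratios against naive were subtracted. Where the naive channel was at background, the Cy5 channels were compared directly after quantile scaling of mean intensity between arrays. The errors of the 2 spots were combined as the root of their summed squares.

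With 1 array per cell type there is no spread between replicates, so no p-value across genes is given. Genes were classed by size alone, at least 2-fold higher or lower. The error of a single value was taken from 3 sources, namely the SD over the 10 spots of replicated probes, the scanner software's error for the spot, and the SD of the naive channel over the 3 arrays. A value given with ± carries the scanner software's error (n = 1 array). A gene-specific dye effect cannot be separated from a difference between naive and polarised cells without a dye swap. It cancels in differences between the cultures. Probes for close gene families (Ifi200, Klra, Ly6, Gzm, class II, Lilr and Apol9 genes among those named) were not tested for cross-hybridisation.

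Lists of genes for T cell lineages, cytokine responses, proliferation, metabolism, stress and other cell types (39 lists) were fixed before the files were read. A list's median log2 ratio over its measured members (at least 3) was placed among 10000 random lists of the same size, matched in 20 bins of mean intensity. A median outside the central 95% of the random lists is called outside the random range. This describes these arrays and is not a test across cultures. Its error is a bootstrap standard error (SE) over genes.

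Genes were named by a rule set beforehand. It takes the members of the Th2, Th9, Treg, TGF-beta and IL-4 lists, the 10 highest and 10 lowest ratios and the 5 highest bounds in each direction of each comparison, and the members with the highest and lowest ratios of each list described. Il2, single genes in the closing section, and the members given as examples for genes shared by comparisons lie in part outside this rule and were then chosen after their values were seen. Where a ratio against naive is given for a named gene and another of its probes differed by more than 2-fold, the text gives both; differences between cultures are by the probe used.

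The size rule was checked on simulated arrays with known changes. For Th2, Th9 and iTreg against naive, 95%, 97% and 96% of 100 true 4-fold changes were called, and 28%, 22% and 24% of 100 true 2-fold changes. Fitted sizes were smaller than true ones, with a median log2 of 1.78, 1.71 and 1.77 for a true 4-fold change. None (0) of the unchanged probes was called. The simulated noise was 0.12 log2 units per channel, and only probes with a brighter naive signal were scored. Few probes were changed, equally up and down. The simulation was thus no strict test of false calls or of the loess scaling. On the Th2 array, 2 of 40 unshifted random lists and 19 of 20 lists shifted by 1 log2 unit fell outside the random range.

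Alternatives covered the background correction, the offset, the dye normalisation, the filter on dim probes, the probe used for a gene, the deposited series values, the size threshold, the link between arrays and the arrays used. Probes with no gene match entered no comparison between cell types.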

Results

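Naive CD4 T cells were sorted by magnetic beads from spleens of C57BL/6 mice aged 6 to 8 weeks. They were stimulated for 3 days with antibodies to CD3e and CD28 (10 µg/ml each) in media that drive different fates. The Th2 medium held IL-2 (1 ng/ml), IL-4 (5 ng/ml) and an antibody against interferon gamma (2 µg/ml). The Th9 medium combined IL-2 (0.2 ng/ml), a lower dose of IL-4 (1 ng/ml) and TGF-beta 1 (2 ng/ml) with more of that antibody (5 µg/ml). The iTreg medium held IL-2 (0.4 ng/ml), TGF-beta 1 (5 ng/ml) and antibodies against interferon gamma and IL-4 (5 µg/ml each). Each polarised RNA was hybridised with naive RNA on 1 array, so all values rest on 1 array per cell type. No culture activated without polarising cytokines was among the samples. A ratio against naive therefore holds the effects of activation and of the medium together.

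Of 43020 spots for genes on each array, 53% to 54% were well above background in the naive channel. In the polarised channel the share was 50.5% for Th2, 48.9% for Th9 and 51.0% for iTreg, and no spot was saturated. The median signal was 88 to 92 in the naive channels over a background of 26 to 28, and 99 to 104 in the polarised channels over a background of 49 to 49.5. Replicated probes had a median SD of 0.047 to 0.052 log2 units over their 10 spots. The scanner software's error had a median of 0.216 to 0.223. The naive channels of any 2 arrays correlated across genes with r of at least 0.998, and 5 to 13 of 11521 genes differed 2-fold between them. The median SD of a gene was 0.048 over the 3 naive channels and 0.263 over the 3 polarised channels.

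The first question was what activation for 3 days had in common in the 3 media. In every culture, genes of cell division, glycolysis and cholesterol synthesis were higher than in naive cells, while genes of the naive state, of the interferon response and of Th1 cells were lower. The mitosis list had 24 of 27 measured members at least 2-fold higher on all 3 arrays, with Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, at log2 3.98 in Th2, 4.10 in Th9 and 2.46 in iTreg. Among 21 measured glycolysis genes, 17 were higher on all 3 arrays. Examples are the lactate transporter Slc16a3 (4.83, 4.78 and 4.91) and triosephosphate isomerase, Tpi1 (4.62, 4.84 and 4.40). Of 22 measured cholesterol genes 17 were higher on all 3, among them Stard4, a sterol carrier, with 3.44 in Th2, 3.47 in Th9 and 2.49 in iTreg (1.32 by its other probe in iTreg). The list of naive and quiescence genes had 11 of 32 members lower on all 3 arrays. Among them was Klf2, a transcription factor of quiescence (-4.91, -3.83 and -1.27).

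Genes of the response to low oxygen were also higher, 10 of 14 on all 3 arrays. The prolyl hydroxylase Egln3 stood at log2 6.33 ± 0.73 in Th2, 6.04 ± 0.70 in Th9 and 5.36 ± 0.65 in iTreg, and Ndrg1 at 4.88, 5.04 and 4.81. Mgarp, a mitochondrial protein, was among the 3 highest genes of every culture (6.27, 6.20 and 5.95). Of 18 measured interferon-stimulated genes 9 were lower on all 3, such as Oas1a (-4.04, -4.39 and -3.61; its other probe gave -2.03, -2.11 and -1.91). Rtp4, another interferon-stimulated gene, had no signal above background in Th2 or Th9 and was lower by at least log2 -6.27 and -6.50, and it stood at -4.94 in iTreg. Of 11 measured Th1 genes 5 were lower on all 3, namely Tbx21, Ifng, Cxcr3, Ccl5 and Ccl3. NK cell markers were lower as well. Whether the Th1 genes fell in T cells or with other cells of the naive preparation was not tested. Of 11 markers of NK and CD8 T cells above background in the naive channel, 8 were at least 2-fold lower or at background in all 3 cultures. The exceptions were Cd8b1, Cd160 and Ctsw. Of 14 myeloid markers 8 met the same rule. Class II antigen presentation genes were higher in all cultures, with 6 of 7 measured members on all 3 arrays and H2-Ab1 at 3.31, 3.32 and 3.32. The B cell marker Cd79b was also higher on all 3 arrays. Few B cell markers were measured (3, 3 and 4 of the list), with medians of -0.77 (SE 1.29), 0.74 (SE 1.05) and 1.05 (SE 0.75), of which only that of iTreg was outside the random range. With bounds they were 0.16, 0.59 and 0.44. Whether B cells contributed was not tested.

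In total 754 genes were at least 2-fold higher and 623 at least 2-fold lower on all 3 arrays, of 10353 measured on all of them. Independent lists would share 25.2 and 20.5. Simulated unchanged groups that share a naive channel shared at most 3 and 4. The simulated noise came only from the spread of the naive channel over the 3 arrays. It held no variation between cultures and no gene-specific dye effect, so it gives no chance level for these counts. The count of 1377 became 2729 without the iTreg array, 1557 without the Th2 array and 1458 without the Th9 array, since fewer arrays had then to agree.

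**Figure D1:**
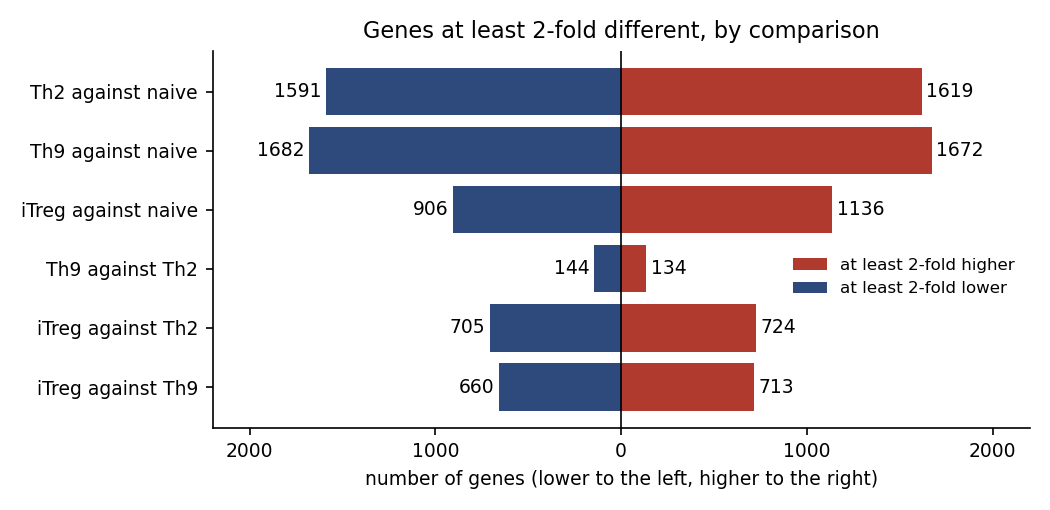
Number of genes at least 2-fold higher (right, red) or lower (left, blue) in each comparison, 1 array per cell type. Th2 and Th9 differed from naive in 3210 and 3354 genes, iTreg in 2042, and Th9 differed from Th2 in 278.

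The comparison of Th2 with naive cells covers activation as well as the IL-4 driven fate. The cytokine genes of this lineage were far higher in Th2 cells. Il4 (NM_021283) was higher by log2 5.08 ± 0.61 (33.7-fold) and Il13 by 4.41 ± 0.56 (21.3-fold), and Il5, at background in the naive channel, was at least 2.64 higher. Gata3, the transcription factor that directs Th2 fate, was higher by 1.40 ± 0.24. Of 13 measured Th2 genes 9 were at least 2-fold higher and 1, the IL-33 receptor Il1rl1, was lower (-1.45). The list's median was 1.87 (SE 0.93), outside the random range.

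Among the other Th2 genes, Nfil3, a transcription factor induced by IL-4, was higher by 4.92, Pparg by 3.34, the chemokine receptors Ccr8 and Ccr4 by 2.54 and 2.32, and Ecm1 by 1.87. Il24 stood at 1.24. Maf, which drives Il4 transcription, was at -0.99, and Il4ra was at -0.53. In the list of IL-4 and STAT6 response genes 8 of 11 were higher, among them Cish (3.31), Gfi1 (2.30), Xbp1 (1.64) and Socs1 (1.19). Bcl6 (-1.45) and Igfbp4 (-1.25) were lower. Much of this was not particular to Th2 cells. Of 10 members of the IL-4 list measured on all 3 arrays, 5 were at least 2-fold higher on each, including iTreg, where IL-4 was blocked. They were Nfil3, Xbp1, Cish, Gfi1 and Slc39a8. Of 10 such Th2 genes 3 were higher on each, namely Ccr4, Ccr8 and Nfil3. Other cytokines were higher in Th2 too, with Il21 at 3.58 and Il3 at 3.34. Il2 itself stood at 1.52 (chosen after its value was seen).

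The highest ratios among measured genes belonged to Asns, asparagine synthetase (6.50 ± 0.73), Egln3 and Mgarp, followed by transglutaminase 2, Tgm2 (5.71, and 4.14 by its other probe), thyroglobulin, Tg (5.67), Fam183b (5.63) and C1qtnf12 (5.54). Vldlr, a lipoprotein receptor, and the growth factor gene Pdgfa were at background in naive cells and at least 4.93 and 4.64 higher. The lowest among measured genes were Ms4a4b (-5.10 ± 0.52), Ifi204 (-4.93), Klf2 and Mndal (-4.87), then Cd1d1 (-4.86) and S100a4 (-4.82). Ifi204, Mndal and Ifi209 (at least -5.92) belong to 1 family of interferon-inducible genes with similar sequences, and whether their probes cross-hybridise was not tested. Of 10947 measured genes 1619 were at least 2-fold higher and 1591 lower (2781 and 810 with median centring in place of loess). A further 279 were at least 2-fold higher and 121 at least 2-fold lower by bounds.

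The comparison of Th9 with naive cells likewise covers activation as well as IL-4 together with TGF-beta. Il9 (NM_008373), the cytokine that names the lineage, had the highest ratio of any measured gene, 6.52 ± 0.81 (91.5-fold). Its naive signal was above background on this array but not on the Th2 array, so the size of this ratio is uncertain. Ahr, the aryl hydrocarbon receptor, was higher by 3.01 ± 0.38, and Il4 was higher by 1.04 ± 0.27. Foxp3, the transcription factor of regulatory T cells, was also higher in this culture (1.28 ± 0.24). Of 11 measured Th9 genes 7 were at least 2-fold higher and 1, Id3 (-1.22), was lower. The list's median was 2.03 (SE 1.03), outside the random range, and 1.32 with members above background in 1 channel set at their bound. The list was outside that range in Th2 (1.61, SE 0.83) and iTreg (0.83, SE 1.00) as well, so it did not single out Th9 cells.

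Transcription factors of this list with high ratios were Bhlhe40 (4.32), Irf4 (3.56), Irf8 (2.17) and Stat5a (2.03). Batf stood at 0.36, and Spi1, the gene for PU.1, was not above background in any culture. Il13 and Il5 were at background in the naive channel of this array and at least 1.26 and 1.76 higher in Th9 cells. Among TGF-beta response genes 6 of 13 were higher, including Gadd45b (2.84), Ldlrad4 (1.82), Skil (1.49) and the receptor Tgfbr1 (1.44), while Smad7 was lower (-1.34). Skil and Tgfbr1 were at least 2-fold higher in both TGF-beta cultures than in Th2. Gadd45b did not follow TGF-beta, being at least 2-fold higher in Th2 and in Th9 than in iTreg. Of 19 Treg genes measured in Th9 against naive, 16 were higher and none lower, led by Socs2 (4.60), Ctla4 (4.18 ± 0.47) and Tnfrsf4 (4.17). Nt5e, which encodes the ectoenzyme CD73, was at 2.50 ± 0.31.

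Dusp4, a phosphatase of MAP kinases, was the next highest gene (6.22), then Mgarp, Asns (6.13) and Egln3. Tubb6 (5.60), Ak4 (5.63) and Serpinc1 (4.26) were also far higher. The lowest among measured genes were Ly6c1 (-5.77, and -4.13 by its other probe), Slfn8 (-5.21), Samd9l (-5.14) and Ms4a4b (-4.97). The receptor gene Vipr1 was at -4.70, with -1.34 by its other probe. Interferon-stimulated genes had a median of -2.42 (SE 0.28), with 16 of 18 measured members lower. Of 10776 measured genes 1672 were at least 2-fold higher and 1682 lower (2311 and 1231 with median centring), and by bounds 274 were higher and 188 lower.

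The third comparison asked what distinguishes TGF-beta induced regulatory T cells from naive cells. Foxp3 (NM_054039) was higher by log2 3.49 ± 0.40 (11.2-fold), and Il2ra, the high-affinity IL-2 receptor chain, by 3.91 ± 0.44. Of 19 measured Treg genes 18 were at least 2-fold higher, and the remaining one, Izumo1r, stood at 0.68. The list's median was 2.34 (SE 0.33), outside the random range, next to 2.23 in Th2 and 2.50 in Th9 cells. The Th2 cytokine genes Il13 (-0.07) and Il5 (0.07) were near naive levels, and Il4 and Il9 were not above background in iTreg. The naive signals of Il13 and Il5 were weak. Il13 was at background in the naive channel of the Th9 array, and Il5 in those of the Th2 and Th9 arrays.

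Other Treg genes with high ratios were Tnfrsf4 (3.69), Ebi3 (3.63), Ctla4 (3.52), Nt5e (3.24 ± 0.37), Lag3 (2.39), Nrp1 (1.64) and Ikzf2 (1.08 ± 0.23). Ikzf4 was at 3.24 by 1 probe and 0.30 by another. Of 13 measured TGF-beta response genes 6 were higher, with Ldlrad4 at 2.64, Pmepa1 at 2.35, Skil at 1.90 and Tgif1 at 1.54. Smad7 stood at -0.38. Among measured genes Bdh2 had the highest ratio (6.23 ± 0.73), and Rgs16 (5.51), Slc9b2 (5.29) and the chemokine receptor gene Ccr6 (4.78 ± 0.52) were also far higher. Granzyme A, Gzma, was the lowest (-6.48 ± 0.67), followed by Ly6c1 (-5.05, and -3.92 by its other probe) and Rtp4. The NK receptor gene Klra4 (-4.02) was also low. Klra8 was at background in iTreg and at least -5.21 lower. NK receptor genes of this family have similar sequences, and cross-hybridisation was not tested.

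Fewer genes differed from naive in iTreg than in the other cultures. Of 11113 measured genes 1136 were at least 2-fold higher and 906 lower (18.4%), against 29.3% for Th2 and 31.1% for Th9. With median centring more were lower (1330) than higher (910). By bounds 152 more were higher and 84 lower. The SD of all log2 ratios was 0.882 on this array, 1.15 on the Th2 array and 1.19 on the Th9 array. Naive and quiescence genes had a median of -0.74 (SE 0.17) in iTreg, -1.86 in Th2 and -1.88 in Th9 cells, but -0.87, -0.99 and -1.13 with median centring, so most of that gap depended on the scaling.

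**Figure D2:**
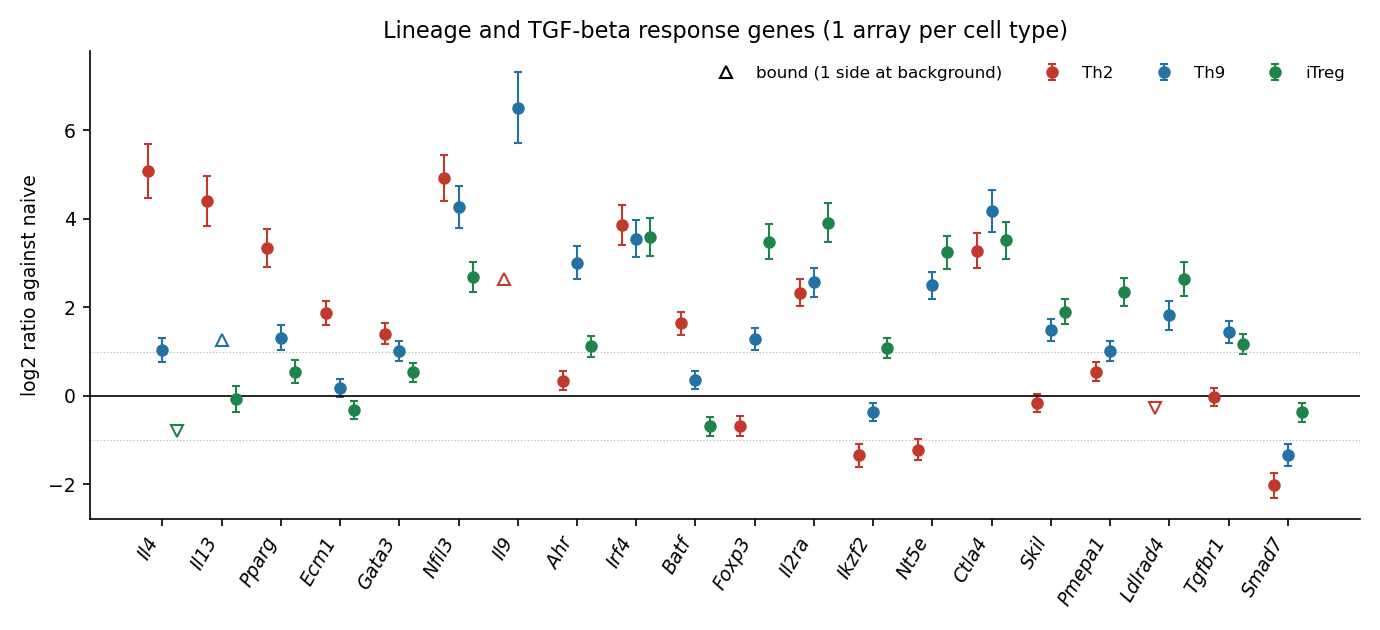
Log2 ratio against naive of lineage and TGF-beta response genes, 1 array per cell type (red Th2, blue Th9, green iTreg), with the scanner software's error as bars and open triangles for bounds where 1 channel was at background. Il4 was highest in Th2 (5.08), Il9 in Th9 (6.52) and Foxp3 in iTreg (3.49).

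Across 10353 genes measured on all arrays, the log2 ratios of Th2 and Th9 correlated with Pearson r 0.950 (Spearman 0.945). The values were 0.767 (0.740) for Th2 and iTreg and 0.818 (0.780) for Th9 and iTreg. These are correlations across genes, which are not independent replicates. Unchanged groups that share a naive channel gave r near 0.50 in simulation, but with a covariance of 0.007 against 1.30, 0.781 and 0.865 here. That simulation had the limits given above. The slope of iTreg on Th2 ratios was 0.591. Genes at least 2-fold different from naive in opposite directions were few: 7 were higher in Th2 and lower in iTreg and 24 the reverse, 1 and 9 for Th9 and iTreg, and 1 and 3 for Th2 and Th9.

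**Figure D3:**
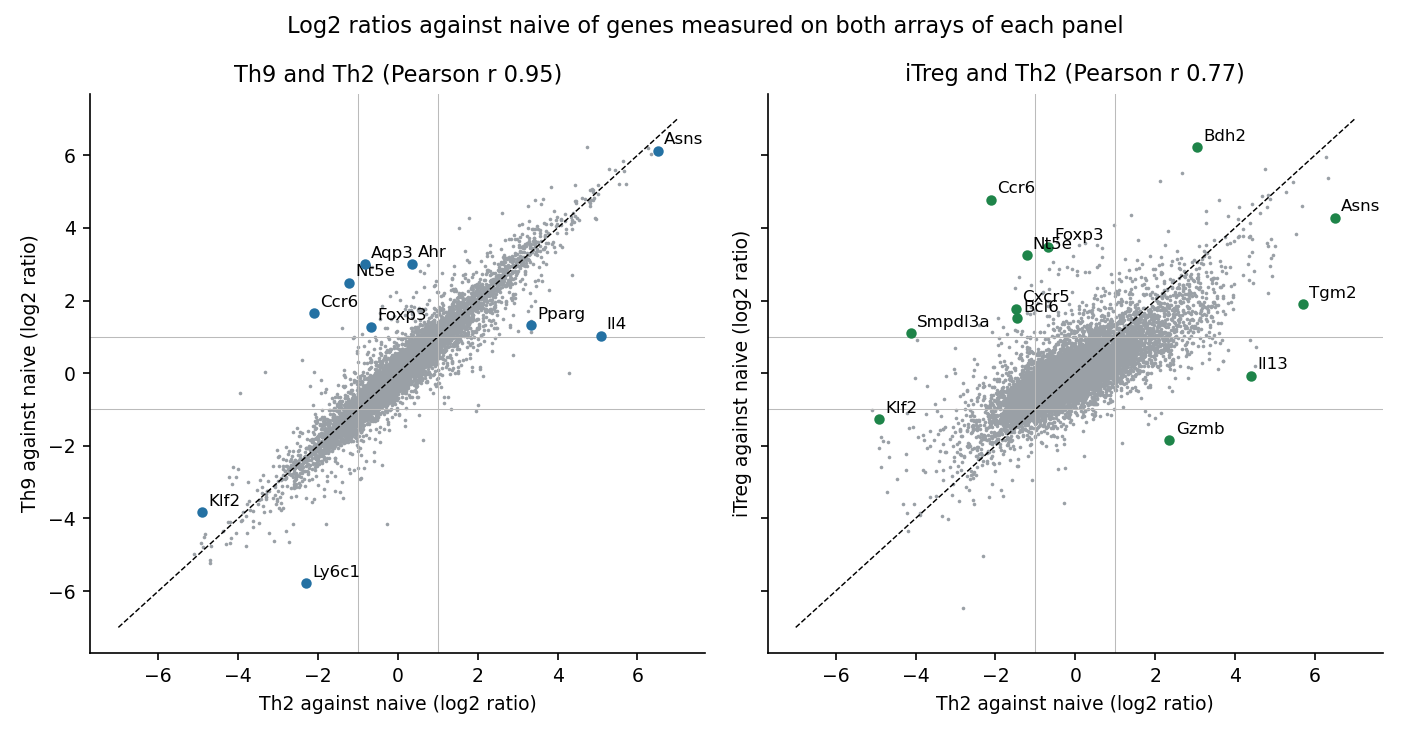
Log2 ratio against naive of each gene in Th9 (left) and iTreg (right) against that in Th2, with the dashed line marking equal ratios and thin lines marking 2-fold. The Th9 and Th2 ratios lay close to the line (r 0.95), and those of iTreg were spread more widely (r 0.77).

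Th9 and Th2 cultures both received IL-4, so their difference addresses the addition of TGF-beta together with less IL-4 and IL-2 and more antibody against interferon gamma (5 against 2 µg/ml). Il4 was lower in Th9 by log2 -4.04 ± 0.67 and Il9 was higher by 4.24 in the direct comparison of channels. Nt5e (3.71 ± 0.40), Ccr6 (3.75 ± 0.46), Ahr (2.67 ± 0.44) and Foxp3 (1.96 ± 0.33) were higher in Th9. Pparg (-2.03), Ecm1 (-1.69), Batf (-1.28) and Il24 (-1.03) were lower, and Il13 was lower by -3.89 in the direct comparison. The Th9 list, whose 10 measured members here leave out Il9, was lower in Th9, with 1 member higher, 3 lower and a median of -0.22 (SE 0.35; -0.31 with bounds and -0.46 with median centring). The median of the Th2 list was -0.52 (SE 0.40) and that of the TGF-beta list 0.44 (SE 0.10; 0.26 with median centring), all 3 lists outside the random range.

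Among genes measured in both channels of both arrays, the water channel gene Aqp3 had the highest ratio (3.85 ± 0.42). Ccr6, Nt5e, Tbc1d4 (3.58), Atp1b1 (3.43), the kinase gene Sgk1 (3.36) and Ctsw (2.76) followed. Serpinc1 (2.49) was also among the 10 highest. TGF-beta response genes that were higher included Skil (1.65) and Tgfbr1 (1.47). Maf was higher by 1.71. Lilrb4a was the lowest of these genes (-4.29 ± 0.60), followed by Il4 (-4.04), Ly6a (-3.87), Ly6c1 (-3.47 by the probe used, whereas its other probe stood at -4.13 in Th9 and -4.05 in Th2), Casp4 (-2.98) and Adam8 (-2.86). Il21 was above background only in Th2 and lower by at least -4.04. The inflammatory chemokine gene Ccl5 was at -2.34. In all, 134 of 10463 measured genes were at least 2-fold higher and 144 lower (2.66%), and bounds added 73 and 62. With median centring the numbers were 102 and 244.

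The iTreg and Th2 cultures differed in TGF-beta, in IL-4 and its blockade, in the dose of IL-2 (0.4 against 1 ng/ml) and in that of the antibody against interferon gamma (5 against 2 µg/ml). Foxp3 was higher in iTreg by log2 4.16 ± 0.46 (17.9-fold), Nt5e by 4.46 ± 0.45 and Ccr6 by 6.88 ± 0.64 (118-fold). Il13 was lower by -4.48 ± 0.63 and Il4 by at least -6.07. The IL-2 and STAT5 response genes were lower, 11 of 18 by at least 2-fold, with a median of -1.32 (SE 0.33; -1.13 with bounds and -2.19 with median centring). The mitosis list was lower for 24 of 27 members with a median of -1.42 (SE 0.09; -2.08 with median centring), and naive and quiescence genes were higher for 19 of 32, with a median of 1.07 (SE 0.16) that was 0.32 with median centring.

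Smpdl3a (5.23 ± 0.51), Atp1b1 (4.88), Ms4a4b (4.08), Acsbg1 (4.06), Apol9b (4.04), Cd7 (3.86) and Ramp1 (3.85) completed the highest genes. Xcl1, a chemokine gene, was at background in Th2 and at least 6.02 higher in iTreg, and Il18r1 was at least 4.05 higher. Plcd1 (-4.29 ± 0.60), granzyme B, Gzmb (-4.21 ± 0.43), the laminin gene Lama5 (-3.81), Tgm2 (-3.81), Gzma (-3.67) and complement C3 (-3.46, with 5.20 in Th2 against naive by its other probe and 3.58 by the one used) were among the lowest. Timd2 was lower by at least -6.54. Among TGF-beta response genes Skil (2.07), Pmepa1 (1.80) and Tgif1 (1.23) were higher, and Gadd45b was lower (-1.52). Pparg (-2.80), Batf (-2.33), Nfil3 (-2.24) and Socs1 (-2.13) were lower as well. Of 10542 measured genes 724 were at least 2-fold higher in iTreg and 705 lower. With median centring in place of loess these numbers were 240 and 2831, since all genes then moved lower by a median of -0.59.

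The iTreg and Th9 cultures both received TGF-beta, at 5 and 2 ng/ml, and differed in IL-4, which was blocked in the former and added to the latter, and in IL-2 (0.4 against 0.2 ng/ml). Il9 was lower in iTreg by at least log2 -6.95. Foxp3 was higher by 2.20 ± 0.47, Ikzf2 by 1.45 ± 0.31 and Nrp1 by 1.46, and Ahr was lower by -1.90 ± 0.45. Other Treg genes went the other way, with Lag3 and Socs2 at least 2-fold lower in iTreg. The median of the Treg list was within the random range with loess and with median centring. Of 9 measured genes of follicular helper T cells 4 were at least 2-fold higher, among them Cxcr5 (3.65 ± 0.43), the inhibitory receptor Pdcd1 (3.47 ± 0.43) and the transcription factor Bcl6 (3.18 ± 0.36). The list's median was 0.63 (SE 1.12), 0.36 with bounds and 0.12 with median centring. The TGF-beta response list had a median of -0.04 (SE 0.31; -0.37 with median centring), within the random range.

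Ms4a4b (3.95), Il18r1 (3.73), Smpdl3a (3.69), Cxcr6 (3.65), H2-Eb2 (3.56) and Samd9l (3.25) were also higher in iTreg. Plcd1 (-4.08), Lama5 (-3.51), Fcmr (-3.46), Batf3 (-3.45), lamin A, Lmna (-3.31), Id1 (-3.21) and the mitotic gene Sgo2a (-2.99) were lower. The mitosis list was lower for 25 of 27 members, with a median of -1.64 (SE 0.08; -2.07 with median centring), and the IL-2 and STAT5 list for 10 of 18 (-1.17, SE 0.42; -1.76 with median centring). Cell surface genes of T cell identity had a median of 0.84 (SE 0.13), with 7 of 17 at least 2-fold higher, but the median was 0.027 with median centring. Of 10474 measured genes 713 were at least 2-fold higher and 660 lower. With median centring the numbers were 320 and 1764, with a median shift of -0.38 for all genes.

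Genes that set iTreg apart from both other cultures numbered 478 lower and 488 higher in iTreg. Both comparisons share the iTreg array, so its own error enters both. The lower ones held 24 of 27 mitosis genes, 13 of 29 S phase genes and 10 of 18 IL-2 and STAT5 response genes, such as Cish, Pim2, Socs2 and Cdkn1a. Il2ra, also of the IL-2 and STAT5 list, was among the higher ones. The higher ones held 14 of 32 naive and quiescence genes, including Klf2, Ccr7 and S1pr1, the T cell receptor genes Cd3e, Cd3g and Cd3d (the last lower in iTreg than in Th2 with median centring), and 9 of 19 chemokine receptor and homing genes. With median centring the numbers became 1586 lower and 167 higher. Genes that set Th2 apart from both TGF-beta cultures were fewer, with 79 lower and 75 higher in Th2 (47 and 165 with median centring). The former held Foxp3, Nt5e, Ccr6, Rora, Skil, Tgfbr1 and Kit. The latter held Pparg, Ecm1, Batf, Gzmb, Il3 and the interferon-stimulated genes Isg15, Oasl1 and Ifih1.

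**Figure D4:**
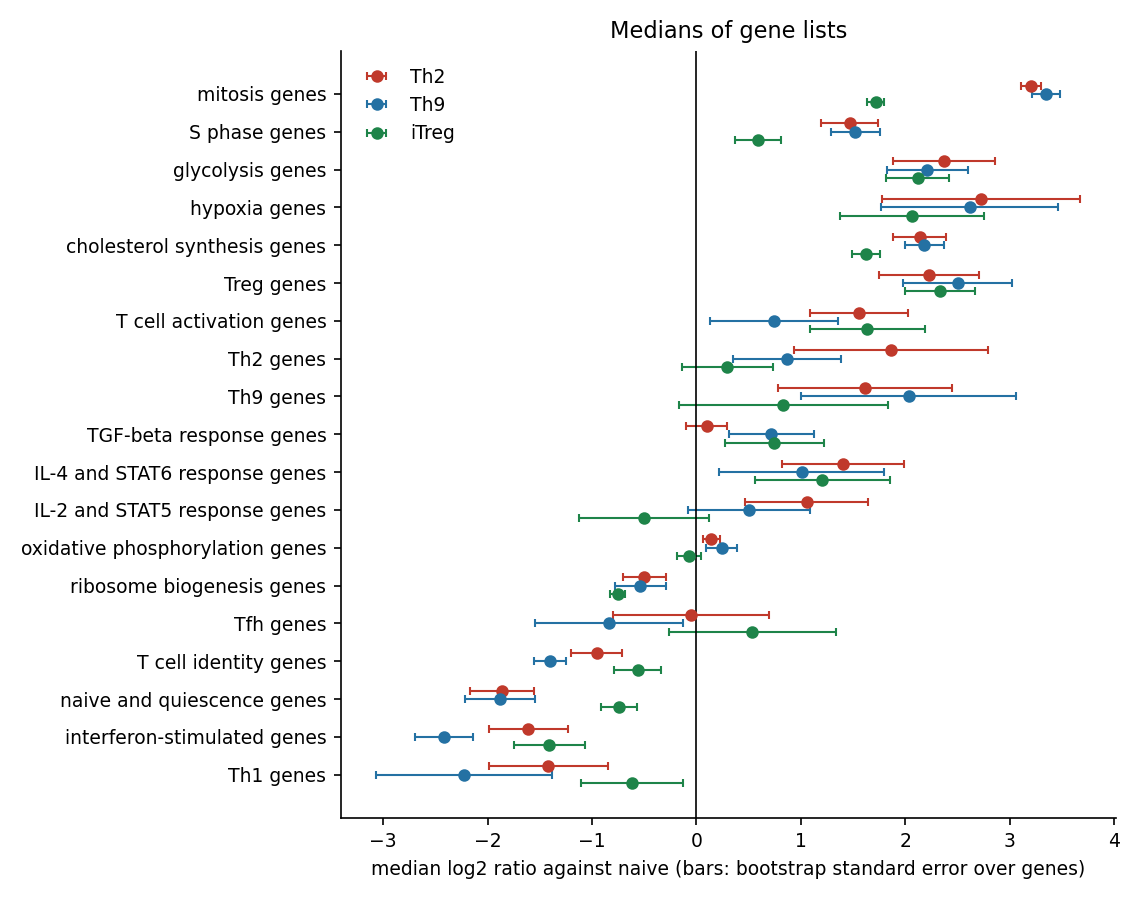
Median log2 ratio against naive of the measured members of 19 gene lists in Th2 (red), Th9 (blue) and iTreg (green), with the bootstrap standard error over genes as bars and 1 array per cell type. Mitosis genes stood at 3.20, 3.35 and 1.72 (3.56, 3.66 and 1.53 under median centring) and glycolysis genes at 2.37, 2.21 and 2.12 (3.57, 3.21 and 2.39); under median centring the T cell identity median of Th2 turns from -0.96 to 0.15.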

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

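The tests on naive-like cells, on compressed ratios, on other cells in the naive preparation and on the IL-2 dose were chosen after the result was seen. Single genes and lists are given here because they lay at least 2-fold (lists: outside the random range) on opposite sides of naive in 2 cultures. With 1 array per culture, none of these differences was tested.

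Among the genes named by the rule, each is given with the cultures in which it was highest and lowest. Highest in iTreg and lowest in Th2 were Ccr6 (log2 4.78 and -2.11), Nt5e (3.24 and -1.22), Apol9b (2.63 and -1.41), Ramp1 (2.33 and -1.52, with -0.08 in Th2 by its other probe), Ctsw (1.33 and -2.40), Rgs2 (1.15 and -1.33, with -0.04 in Th2 by its other probe), Smpdl3a (1.11 and -4.12) and Ikzf2 (1.08 and -1.35). Highest in iTreg and lowest in Th9 were H2-Eb2 (2.02 and -1.54), Cxcr5 (1.78 and -1.87), Bcl6 (1.52 and -1.66) and Ccl4 (1.18 and -1.16), of which Cxcr5 (-1.49) and Bcl6 (-1.45) were lower than naive in Th2 too. Gzmb (2.36 and -1.85) and Adam8 (1.99 and -1.25) were higher in Th2 and lower in iTreg. Lmna was higher in Th9 (2.27) and lower in iTreg (-1.04), and Casp4 higher in Th2 (1.95) and lower in Th9 (-1.04).

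The Th17 gene list had a median of 2.30 in iTreg (5 measured) and -0.997 in Th2 (6 measured), but with bounds included these were 1.26 and 0.11, on the same side of naive, and with the brighter genes alone the iTreg median was -0.67. Its member Rora was higher in iTreg than in naive cells (2.30), but it was at least 2-fold higher than naive in Th2 and Th9 as well. Il17a, at background in the naive channel, was at least 1.26 higher in iTreg. The Tfh list stood at 0.53 in iTreg and -0.84 in Th9 (0.092 and -0.33 with bounds included), and the IL-2 and STAT5 list at 1.06 in Th2 (1.72 with median centring) and -0.50 in iTreg (-0.58). Among probes matched to no gene, 417 were at least 2-fold different from naive in the same direction on all 3 arrays (240 higher and 177 lower, of 3997 measured on all arrays), and no gene comparison used them.

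Differences from naive were smaller on the iTreg array. If cells still like the naive preparation were the whole cause, 1 share of such cells would serve every list, but mitosis genes needed 73.5% (95% interval 70.4 to 76.2) and glycolysis genes 27.4% (14.4 to 37.6). If all log2 ratios of that array were compressed alike, the iTreg ratio would be 1 fraction of the mean of Th2 and Th9, but it was 0.531 (0.479 to 0.576) for mitosis and 0.883 (0.793 to 0.930) for glycolysis genes. With median centring the shares of mitosis and glycolysis genes were 83.9% (82.2 to 86.4) and 63.1% (55.7 to 67.7). The fractions were then 0.409 and 0.677. Mitosis and glycolysis thus stayed apart, but the shares only just beyond the limit of 20 points set for this test. With loess, S phase genes needed 69.5% (66.3 to 78.2) and cholesterol synthesis genes 35.1% (23.0 to 53.5). Naive and quiescence genes needed 37.6% (25.9 to 49.0). By share, the cell division lists stood apart from the others. By fraction of the log2 ratio they did not. Naive and quiescence genes stood at 0.400 (0.337 to 0.587), with an interval overlapping those of mitosis and S phase genes (0.464, 0.430 to 0.510). Cholesterol synthesis genes stood at 0.790 (0.711 to 0.867), near glycolysis genes. Naive-like cells and compressed ratios are argued against as sole causes, the former weakly with median centring, and not as contributions. A smaller share of naive-like cells together with less division was not tested. The medium, with TGF-beta and without IL-4, stays open and untested. Array position goes with the cell type. Between arrays 5 to 13 of 11521 genes differed 2-fold in the naive channel, which argues against an effect of position on both channels, while one on the Cy5 channel alone stays open.

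Most NK cell markers and 8 of 14 myeloid markers were lower in all 3 cultures, while Cd8b1, Cd160 and Ctsw of the NK and CD8 list were not. Weak signals sinking below background are argued against as the cause, since 9.04% of genes matched on naive level met the same rule, against 64% of the markers (16 of 25). Other cells in the naive preparation that were lost in culture may explain it. That share lies between the limits set for this test (75% and 50%), so the test left this open. The purity of the bead-sorted naive cells was not tested. Markers of other cells also met the rule, 3 of 6 for mast cells and basophils and 3 of 5 for erythroid cells and platelets. The numbers were 3 of 7 for dendritic cells, 1 of 4 for B cells and 0 of 3 for stromal cells. In the naive channel the markers Klrd1, S100a9 and Fcer1g had log2 signals of 11.77, 11.41 and 11.38, which give no share of cells, since probes differ in signal. Loss of these transcripts from T cells themselves was not tested.

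IL-2 and STAT5 response genes were lower in iTreg than in Th9, with a median of -1.17 (SE 0.417), although the iTreg medium held more IL-2 (0.4 against 0.2 ng/ml). This argues against the added dose as the whole cause. Th9 against Th2 (0.2 against 1 ng/ml) went the way of the dose (-0.28, 95% interval -0.59 to -0.057), and IL-2 made or used by the cells was not measured. Il2ra, a member of the list, was instead at least 2-fold higher in iTreg than in Th2 and Th9. Fewer dividing cells could be another cause. The 9 members less than 2-fold higher than naive in Th2 and Th9 had a median of -0.29 (SE 0.317, 95% interval -1.28 to 0.049), within the limit set beforehand for this explanation. The interval also holds the median of the whole list and the members were picked partly by their Th9 value, so, with a stricter reading adopted after the value was seen, division and a weaker IL-2 response cannot be told apart. Nor can either be told apart from IL-4, which was added to Th2 and Th9 and blocked in iTreg. Cish and Socs1, lower in iTreg than in both, are in the IL-4 list as well.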

How the results depend on the processing

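The alternatives were chosen before the data were examined, except those for genes named outside the Th2, Th9 and Treg lists and the direct difference for single genes, which were added after seeing the data. No paired analysis was possible because each culture had 1 array. Arrays held about 50% of spots above background, so genes near background have bounds or no value, and the size rule called few true 2-fold differences on simulated arrays. Filters on dim probes leave a single gene's value as it is, so they gave no value of their own for named genes.

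With the 2-fold rule kept, counts against naive were 1703 to 3917 for Th2, 1751 to 4049 for Th9 and 1092 to 2745 for iTreg, and iTreg had the fewest under each alternative. Correlations were 0.937 to 0.955 (Th2 and Th9), 0.748 to 0.782 (Th2 and iTreg) and 0.805 to 0.832 (Th9 and iTreg). Of 122 counts and correlations under alternatives, 91 stayed within their limit (1.5 times for counts, 0.05 for correlations) and 31 did not. Adding the scanner software's p under 0.01 left the counts against naive and the count on all 3 arrays as they were, and was not run between cultures. The scanner error had a median of 0.216 to 0.223 log2 units, so a 2-fold ratio would rarely fail that limit. These unchanged counts, which are among the 91, were thus no strict check. List medians outside the random range numbered 148 of 229, and 114 to 144 under alternatives; between cultures 68, and 65 by direct difference.

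In the order Th2, Th9 and iTreg against naive, Th9 against Th2, iTreg against Th2, iTreg against Th9, all 3 arrays, both against Th2 and both against iTreg, genes in the upper part of mean intensity (above its median) gave 1703, 1751, 1092, 111, 712, 658, 769, 67 and 477, fewer because fewer genes entered. A 1.5-fold rule gave 5465, 5663, 4154, 817, 3460, 3400, 2884, 448 and 2551, and a 3-fold rule 1518, 1598, 795, 80, 432, 389, 523, 41 and 240, by construction. Leaving out 1 array, genes alike on the others numbered 1458 to 2729 (2729 without iTreg), as fewer arrays had to agree.

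Median centring in place of loess shifted the median of all genes by 0.35 (Th2), 0.18 (Th9), -0.16 (iTreg), -0.22 (Th9 against Th2), -0.59 (iTreg against Th2) and -0.38 (iTreg against Th9). It gave 3071 genes for iTreg against Th2 (7.82% higher), 2084 for iTreg against Th9 (15.4% higher) and 1753 for both against iTreg (90.5% higher in Th2 and Th9). Of 1684 list medians under alternatives 222 moved by more than their limit (111 of 229 with median centring), and of 1092 outside the random range 1000 stayed outside. In all 92 medians (32 with median centring) lay on the other side of 0. Of these 14 belonged to lists outside the random range in the main values and are given as reversed, and the other 78 to lists within it. With median centring the reversed ones were Th1 genes (-0.12), T cell identity genes (-0.35) and myeloid markers (-0.0050) in iTreg against Th2, T cell identity genes in Th2 against naive (0.15), and mitosis (-0.0020) and oxidative phosphorylation genes (-0.14) in Th9 against Th2. With no filter they were Th17 genes (-0.13) and dendritic cell markers (0.022) in iTreg against Th9 and cytotoxic genes in Th2 against naive (0.036). With the brighter genes they were Th1 (-1.58) and cytokine genes (0.57) in iTreg against Th2, Th17 genes in Th9 (-1.74) and iTreg (-0.67) against naive, and cytokine genes in Th9 against Th2 (0.19). Of 4382 values of named genes under alternatives 926 moved and 3 reversed, each of Cd3d with median centring: 0.39 in Th2 and 0.14 in Th9 against naive, and -0.017 in iTreg against Th2. The cause was not tested.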

Other observations

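Metabolic genes beyond glycolysis and cholesterol synthesis had smaller medians with loess, which median centring moved. Fatty acid oxidation genes had medians of 0.59, 0.65 and 0.55 in Th2, Th9 and iTreg (1.43, 1.14 and 0.33 with median centring), with Acads (1.52, 1.66 and 1.53) and Decr1 (1.39, 1.60 and 1.51) at least 2-fold higher in each. The desaturase Scd2 was higher by 4.82, 4.61 and 3.50. Oxidative phosphorylation genes stood at 0.14, 0.24 and -0.07 (1.26, 1.07 and 0.03 with median centring, where the iTreg sign turns), with 0, 1 and 0 of 26 measured members at least 2-fold higher. Serine and one-carbon genes had medians of 0.89, 0.61 and 0.20 (1.32, 0.97 and 0.011 with median centring); Psat1 was at 2.94 in Th2 (1.71 by its other probe), 2.62 in Th9 and 0.84 in iTreg, and Shmt2 at 1.25, 1.27 and 0.02. The list of ATF4 and unfolded protein response genes was lower in iTreg than in Th2 (-1.08, or -1.72 with median centring, 10 of 19 lower), with Hsp90b1 at 0.44 in Th2 and -1.25 in iTreg.

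Early response and stress genes were lower than naive in every culture for 5 of 14 members measured on all arrays, among them Hsph1 (-2.74, -2.64 and -3.14), Fos (-2.56, -3.04 and -2.79), Jun (-2.62, -2.15 and -1.28) and Dnajb1 (-2.38, -2.43 and -1.74). The median of this list was within the random range in Th2 and Th9 and outside it only in iTreg. Ribosome biogenesis genes had medians of -0.50 in Th2 (0.072 with median centring), -0.54 in Th9 and -0.75 in iTreg, the last outside the random range, with Polr1b (-1.22, -1.66 and -1.56) and Bop1 (-1.56, -1.72 and -1.19) lower in each. Genes for chemokine receptors and homing were lower in Th2 (13 of 20), Th9 (11 of 19) and iTreg (8 of 19), such as Ccr9 (-2.45, -2.61 and -2.04) and Itgb7 (-2.39, -2.58 and -1.90). Class II genes included H2-DMb1 (3.48, 3.41 and 1.93) and H2-Oa (2.55, 2.58 and 3.13), while H2-Ob was lower in Th2 (-1.36) and Th9 (-1.35). Probes of 1 gene lay over 2-fold apart for 435 of 2574 genes on the Th2 array (16.9%) and for 156 of 2660 on the iTreg array (5.86%).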
